A study of Mus musculus with 4 samples.

How the data were processed

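Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on hippocampus from adult C57BL/6N mice with an antibody against TIMELESS. There were 3 TIMELESS ChIP libraries and 1 input library, which is chromatin that went through no immunoprecipitation. Per the labels' protocols, tissue was fixed with formaldehyde and chromatin was sonicated before immunoprecipitation. The labels do not say that the 3 ChIP libraries came from separate animals, so the spread between them may be technical.

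The authors deposited 1 list of peaks per library. Per the file headers, peaks were called with MACS 2.1.2, separately for each library and with no control library, at a q value cutoff of 0.05. The headers give the caller's own mouse genome size, reads of 101 bp treated as single-end, and at most 1 tag kept per position. Per the submitters' processing notes, the build was mm10 and the tools included Bowtie2 2.4, SAMtools 1.14, MACS2 2.1.1 and deepTools 2.0. The MACS version in the notes differs from that in the headers, and the aligner's settings were not given in the sources used here.

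Each deposited peak had a start, an end, a width and a summit. The deposited pileup was the signal (fragment coverage) at the summit after removal of duplicate positions, in raw units not scaled for depth. The deposited fold enrichment compared that pileup with the caller's background of the same library, for which the headers give a range of 10 kb. That background was not always local. In replicate 3, the Pde4b peaks starting at 102133394 and 102347832 both had pileup 28 and fold 5.54, so a background common to distant sites entered too. Folds may therefore depend on depth. The deposited p and q values were given as −log10 values, per the file headers. Since no input entered the calling, a site where any library of this tissue piles up reads can be called a peak. Fold, p and q values are the authors' own for each peak and were used to describe, rank or filter peaks.

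The header of the peak list of TIMELESS replicate 3 names its alignment file and its peaks as a second input, while the labels call the library TIMELESS. The group in the labels was kept, the library is called the library labelled TIMELESS replicate 3 or replicate 3, and each leading count is also given without it.

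Per the file headers, MACS read 15309951, 24208455 and 57951401 tags for TIMELESS replicates 1, 2 and 3 and 27512636 for the input. After removal of duplicate positions it kept 8425679, 13572739, 30454118 and 14669253 tags. Deeper libraries allow weaker sites to pass the same q value, so the number of peaks depends on depth as well as on enrichment.

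Peaks on chromosomes 1 to 19, X and Y were used, with coordinates as the files give them. Peaks on the mitochondrial sequence and on a sequence named ribosomic were left out of the comparisons. Overlapping peaks of the 3 TIMELESS libraries were merged into regions, with a minimum overlap of 1 bp. Regions over an input peak were left out. A shared region held peaks of at least 2 libraries. The fold of a library in a region was that of its highest peak there. Chance was measured by a permutation of peak positions, placing each library's peaks at random on their own chromosomes with widths kept, in 1000 draws, between the first and last peak of any library. The smallest p these draws can give is 9.99e-04 one-sided and 0.0020 two-sided. Tests of overlap were one-sided and tests of position and of gene lists were two-sided. Peaks are the units of these tests, and neighbouring peaks are not independent. With 3 libraries against 1, an exact permutation test cannot give a p below 0.25, so no test between ChIP and input libraries was made.

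Gene positions came from a RefSeq gene table of the assembly GRCm38.p6, which is the build of the files, with 49943 genes of which 21887 were protein-coding on the chromosomes used. The table gave the start and end of each gene without strand, transcription start site, exons or introns, and no genome sequence was used here. The planned share of summits in promoters was therefore replaced by the share within 1 kb of either end of a protein-coding gene. The planned window of a gene body and 3 kb upstream was replaced by the body and 3 kb on both sides. Whether a site is exonic or intronic was not analysed here.

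There were 18 gene lists with 424 entries, of which 421 matched the table. For each list, the share of members with a shared region was compared with 10000 random lists matched on 10 classes of gene length, which permutes list membership among genes of like length, and p values were adjusted over the 18 lists by the Benjamini-Hochberg method. Named genes were chosen by a rule. It took the 15 protein-coding genes that held a region of all 3 libraries and had the largest smallest fold, then up to 4 members of each list ranked by number of libraries and smallest fold. It also took Timeless and Pde4b whatever their values, and the 10 regions with the largest smallest fold. Some genes the rule takes are not reported here. The groups, tests, lists, naming rule and a set of other settings were fixed before the data were examined.

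The other settings fixed in advance were peaks with −log10 q of at least 5, peaks with fold of at least 5, 50% reciprocal overlap, input regions kept, equal numbers of top peaks, other gene windows, unmatched lists and leaving out each library. Settings chosen after seeing the data were moving each peak by 10 to 500 kb, matching each list member to the 100 protein-coding genes nearest in length, the windows at either gene end, and leaving out each library where that was not planned.

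The procedures were tested on simulated data. In 40 runs with independent libraries, 1 gave p of 0.05 or less for sharing. These runs used the same random placement as the test, so they do not show that it suits real peaks. Among 500 sites planted at the same coordinates in all 3 libraries, 100% of those off input peaks were found in all 3. Merging of overlapping peaks must give that result, so it checked the computation only. In 40 runs with random summits, 3 gave p of 0.05 or less for the share in genes. Where genes were hit by length alone, matching on classes of length called 1 of 18 lists, matching to the nearest genes called 0 and no matching called 5. Intervals are exact Clopper-Pearson intervals at 95% and cover counting error only. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.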

Results

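The data comprised 3 hippocampal libraries immunoprecipitated with an antibody against TIMELESS, a protein known from the circadian clock and from the replication fork, and 1 input library. The peak caller kept 8425679, 13572739 and 30454118 tags in TIMELESS replicates 1, 2 and 3 and 14669253 in the input. The file header of the library labelled TIMELESS replicate 3 names an input, so counts are also given without that library. The title of the study links TIMELESS to synaptic plasticity, memory and cAMP signalling. The comparisons therefore addressed where TIMELESS peaks lay, whether the libraries shared them, and whether genes of cAMP signalling and of the synapse held them.

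TIMELESS libraries had many more peaks than the input. On chromosomes 1 to 19, X and Y, replicates 1, 2 and 3 had 7454, 24659 and 89043 peaks, a mean of 40385 ± 43008 (SD, n = 3), and the input had 306. The TIMELESS library with the fewest peaks had 24.4 times as many as the input although it held fewer tags. Per 1000000 tags kept, the TIMELESS libraries had 885, 1817 and 2924 peaks and the input had 20.9. TIMELESS peaks covered 2.99, 9.89 and 43.7 Mb of the genome, and input peaks covered 0.115 Mb. The peak counts are not at a common strength. The smallest −log10 p of a peak was 3.85, 3.5 and 3.21 in replicates 1, 2 and 3 and 6.07 in the input. At −log10 p of at least 12.1, replicates 1, 2 and 3 kept 915, 2231 and 2754 peaks, against all 306 input peaks. That cutoff, chosen after the results were seen, was not applied to the input, and replicate 3 was scaled to the depth of the input.

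The median fold enrichment was 4.91, 4.41 and 3.63 in TIMELESS replicates 1, 2 and 3 and 5.52 in the input. Each fold is relative to the background of its own library, and depth may enter it. The spread of the peak counts between TIMELESS libraries was as large as their mean, and without replicate 3 the mean fell to 16056 peaks. With a single input library the difference from the input has no replicate check. At −log10 q of at least 5 the mean was 22932 TIMELESS peaks against 250 in the input, and at fold of at least 5 it was 7984 against 184.

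**Figure D1:**
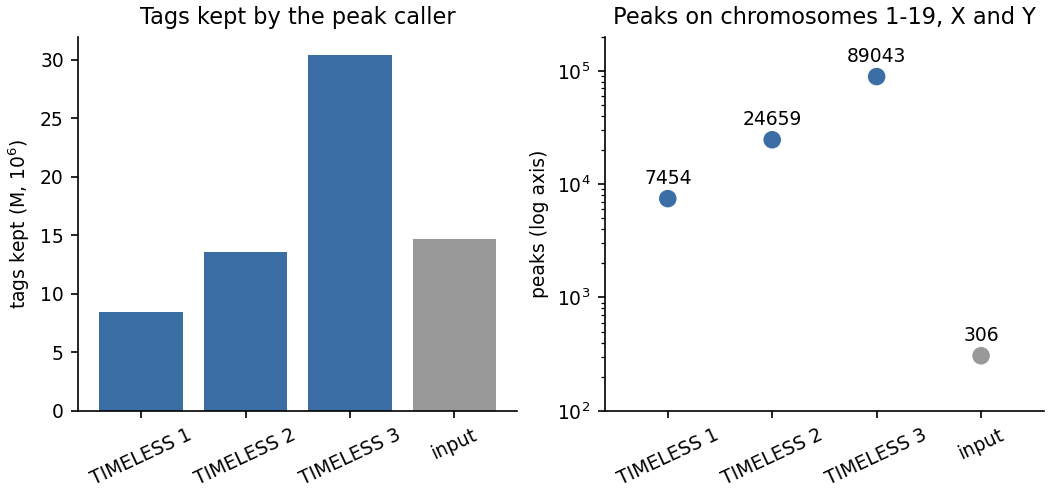
The left panel shows bars of the tags kept by the peak caller in each library, in units of 1000000 tags, and the right panel shows points for the number of peaks on a log axis; TIMELESS libraries are blue and the input is grey. The input has 306 peaks and each TIMELESS library has at least 7454, with tag numbers between 8425679 and 30454118.

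The 3 TIMELESS libraries placed peaks at the same sites far more often than chance. A total of 11957 regions held peaks of at least 2 libraries, 11.9 times the 1007 ± 31.4 regions (SD over 1000 random placements) expected. Peaks of all 3 libraries met in 3476 regions, against 2.86 ± 1.71 at random. Ranked by the smallest fold over the 3 libraries, the first of these regions lay in Gm525, a predicted gene on chromosome 11 (89073841 to 89093064), where the region at 89081625 to 89082195 had folds of 20.6, 20.6 and 20.9 in replicates 1, 2 and 3, a mean of 20.7 ± 0.172 (SD, n = 3). Both counts exceeded each of the 1000 random placements, which gives a permutation p = 9.99e-04, the smallest they can give. Peaks of replicates 1, 2 and 3 also met input peaks 231, 76.7 and 20.4 times as often as at random. An excess over random placement therefore does not by itself show binding by TIMELESS, although regions over input peaks were left out.

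The 15 protein-coding genes taken by the naming rule, ranked by the smallest fold of a region of all 3 libraries, were of varied kinds, and no theme was tested among them. Input peaks reached folds of up to 33.1, and repeats were not tested. A high fold therefore does not by itself show binding by TIMELESS at these genes. Grk5, a kinase that phosphorylates activated G protein-coupled receptors, held a region on chromosome 19 at 60924487 to 60924971 with a mean fold of 19.6 ± 1.03 (SD, n = 3). Esr1, which encodes oestrogen receptor alpha, held one on chromosome 10 at 4730083 to 4730616 with 16.8 ± 2.88. Asmt, the enzyme of the last step of melatonin synthesis, held one on chromosome X at 170672842 to 170673763 with 19.4 ± 2.22. Stk32c, a serine/threonine kinase, had a mean fold of 13.7 ± 1.29.

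Cntnap5c, of the contactin-associated protein family, held a region on chromosome 17 at 57855845 to 57856513 with a mean fold of 20.7 ± 1.51 (SD, n = 3). Rims1, a scaffold of the presynaptic active zone, held one on chromosome 1 at 22327473 to 22327992 with 14.1 ± 0.905. Nkain3, which encodes a partner of the sodium pump, held one on chromosome 4 at 20191665 to 20192134 with 15.6 ± 1.44. Slc45a1, a sugar transporter, had a mean fold of 13.3 ± 1.27.

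Immp2l, a subunit of a mitochondrial inner membrane peptidase, had a mean fold of 16.2 ± 1.10 (SD, n = 3). The predicted gene Gm11213 had 18.3 ± 0.212. Tekt4, a tektin of ciliary microtubules, had 15.1 ± 1.66 in a region outside the gene and within 3 kb of it. F13a1, a subunit of coagulation factor XIII, had 12.9 ± 1.75, and Cep128, a centrosomal protein, had 11.9 ± 0.511.

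Of the 10 regions with the largest smallest fold, 6 lay in the genes Gm525, Cntnap5c, Grk5, Gm11213, Asmt and Immp2l. The other regions overlapped no protein-coding gene. The region on chromosome 5 at 38022924 to 38023487 had a mean fold of 21.4 ± 1.01 (SD, n = 3) and lay 13.2 kb from Stx18. The region on chromosome 9 at 123924285 to 123924761 had 18.2 ± 1.99 and lay 37.4 kb from the chemokine receptor gene Ccr1. The region on chromosome 2 at 58425860 to 58426563 had 15.7 ± 1.06, lay 19.9 kb from Acvr1 and overlapped the uncharacterised gene LOC108168760. The region on chromosome Y at 5806233 to 5806855 had 16.5 ± 2.23 and lay 78.1 kb from Gm20914.

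Replicate 3 alone accounted for 77988 regions, replicate 2 alone for 13145 and replicate 1 alone for 1755. Of the peaks of replicate 1, 65.7% overlapped a peak of replicate 2 (95% interval 64.6 to 66.8), against 0.748% at random, and 58.4% overlapped a peak of replicate 3, against 2.98%. Of the peaks of replicate 2, 41.3% overlapped a peak of replicate 3. Of the more numerous peaks of replicate 3, 4.91% and 11.5% overlapped peaks of replicates 1 and 2.

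The count of shared regions fell from 11957 to 4725 without replicate 3, to 4193 without replicate 2 and to 9905 without replicate 1. The 4725 regions of replicates 1 and 2 were 85.3 times the random number. Stricter thresholds lowered the counts, to 4956 shared regions and 1544 in all 3 libraries at −log10 q of at least 5, and to 2511 and 913 at fold of at least 5.

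**Figure D2:**
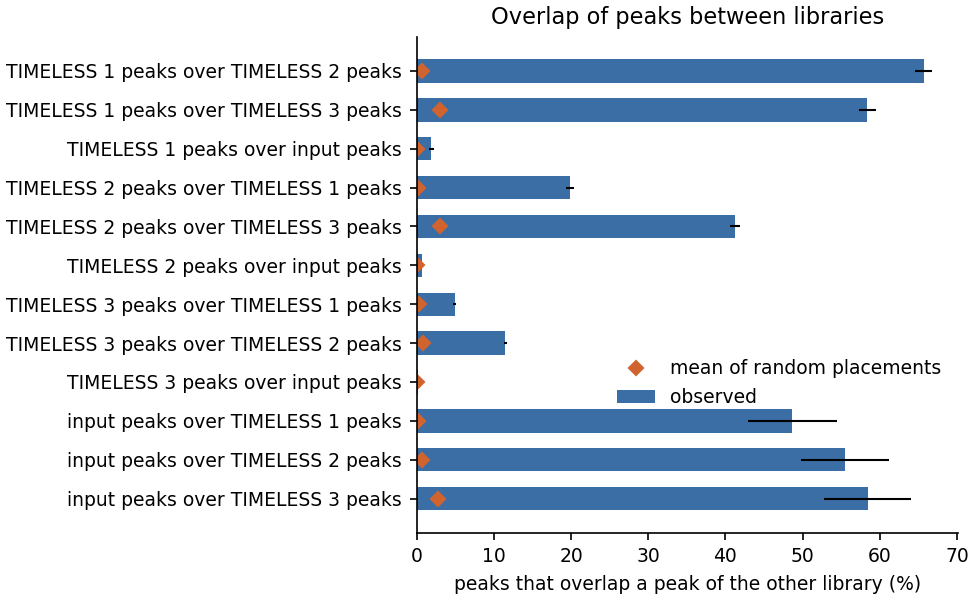
Bars give the percentage of each library's peaks that overlap a peak of another library, black lines give exact 95% intervals, and diamonds give the mean of 1000 random placements. Between TIMELESS libraries the observed share reaches 65.7%, random shares stay at or below 2.98%, and TIMELESS peaks over input peaks are at most 1.89%, a share that the 306 input peaks bound.

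TIMELESS peaks lay over input peaks more often than chance. The shares were 1.89%, 0.657% and 0.191% in replicates 1, 2 and 3, a mean of 0.913% ± 0.879 (SD, n = 3). Random placement gave 0.00871%. The number of input peaks bounds these shares, which would be 4.11%, 1.24% and 0.344% if every input peak held 1 TIMELESS peak. In the other direction, 48.7%, 55.6% and 58.5% of the 306 input peaks overlapped a peak of replicates 1, 2 and 3, so most sites called in the input recurred in replicates 2 and 3. Leaving out regions over input peaks removed 151 shared regions, of which 129 held peaks of all 3 libraries.

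Each overlap with the input exceeded all 1000 random placements, with permutation p = 9.99e-04, the smallest they can give. Without replicate 1 the mean share fell to 0.424%, and at −log10 q of at least 5 it was 1.95%.

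Strong sites in one TIMELESS library tended to be strong in the others. Across the 3476 regions of all 3 libraries, Spearman's rho of fold enrichment was 0.627 between replicates 1 and 2, 0.595 between 1 and 3, and 0.677 between 2 and 3. Pearson's r was 0.774, 0.696 and 0.739. The median fold in these regions was 5.19, 5.33 and 4.14 in replicates 1, 2 and 3. The serotonin receptor gene Htr4 had nearly equal folds of 10.7, 10.7 and 10.6, and the glutamate receptor gene Grm5 had folds of 5.24, 4.45 and 10.9. These correlations are across regions, which are not independent replicates, and no p was computed.

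TIMELESS summits lay inside genes, and near gene ends, less often than chance. The share of summits inside annotated genes was 36.5%, 34.8% and 32.6% in replicates 1, 2 and 3, a mean of 34.6% ± 1.95 (SD, n = 3), against 47.4% at random. Inside protein-coding genes it was 26.4% ± 1.52, against 39.2%, and the input share of 27.8% (95% interval 22.8 to 33.2) was likewise below its random 39.1%. Within 1 kb of either end of a protein-coding gene it was 0.926%, 0.767% and 0.554%, a mean of 0.749% ± 0.187, which is 3.94-fold lower than the 2.95% at random, and within 3 kb it was 3.27% ± 0.541, against 7.97%. Of the 3476 regions of all 3 libraries, 25 had their midpoint within 1 kb of a gene end, or 0.719% (95% interval 0.466 to 1.06).

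Each TIMELESS library differed from random placement in the share in genes and in the share near gene ends, with two-sided permutation p = 0.0020, the smallest the draws can give. Input summits lay inside genes in 43.8% of cases (95% interval 38.1 to 49.5), against 46.8% at random with permutation p = 0.280, and inside protein-coding genes they too were rarer than at random, with two-sided permutation p = 0.0020. Within 1 kb of a gene end the input share was 5.88% (3.52 to 9.14), above the 3.05% at random with permutation p = 0.0120, but within 3 kb it was 9.80%, against 8.11% with permutation p = 0.316. The gene table has no strand, so starts and ends of genes were not told apart. When each peak was moved by only 10 to 500 kb, a comparison chosen after seeing the data, the random share near gene ends was 2.56% and all 3 TIMELESS libraries stayed below it.

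**Figure D3:**
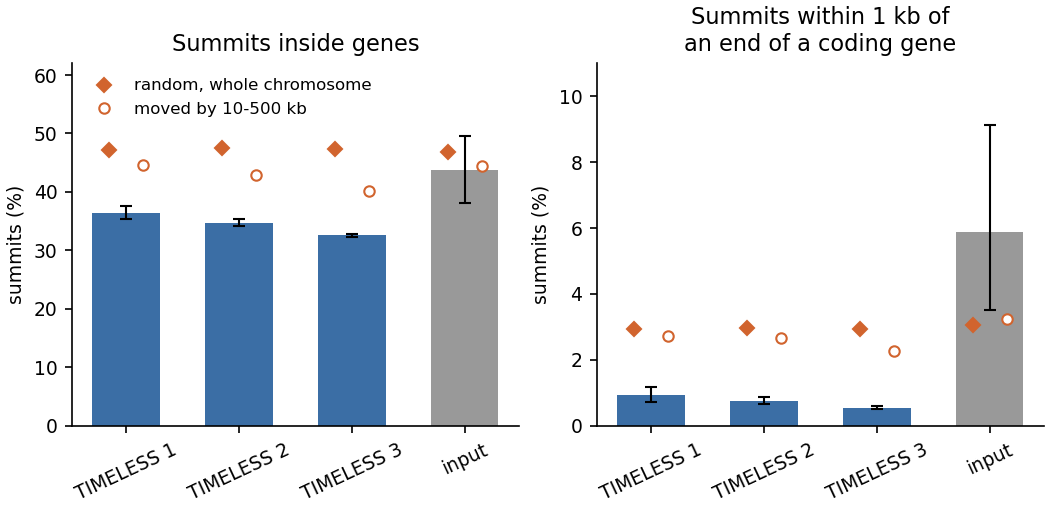
Bars show the percentage of summits inside annotated genes (left) and within 1 kb of an end of a protein-coding gene (right) in each library, with exact 95% intervals; filled diamonds show random placement on the chromosome and open circles peaks moved by 10 to 500 kb. All 3 TIMELESS libraries lie below both random values in both panels, and the input lies above them near gene ends at 5.88%.

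Shared regions fell in or within 3 kb of 2172 of the 21887 protein-coding genes, or 9.92%, and 915 genes held a region of all 3 libraries. Regions with peaks of both replicates 1 and 2 fell in 1223 genes. They were merged over all 3 libraries, so this count is not free of replicate 3. Long genes held shared regions most often. The share rose from 1.60% in the shortest of 10 classes of gene length to 47.3% in the longest, where genes span at least 108.5 kb.

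Pde4b, a phosphodiesterase that degrades cAMP, held 1 region with peaks of all 3 TIMELESS libraries. Pde4b spans 519.9 kb of chromosome 4 (102087332 to 102607275, mm10), and the region lay inside the gene at 102493927 to 102494914. Its folds were 7.15, 5.82 and 7.98 in replicates 1, 2 and 3, a mean of 6.98 ± 1.09 (SD, n = 3). Replicate 2 had 1 further peak in the gene and replicate 3 had 9 further peaks, none of which met a peak of another library. Timeless itself, at 128232063 to 128252941 on chromosome 10, held no region of any of the 3 libraries, with regions over input peaks left out. Among the 100 protein-coding genes nearest in length to Pde4b, 41 held a region of all 3 libraries, and among those nearest to Timeless 1 did.

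**Figure D4:**
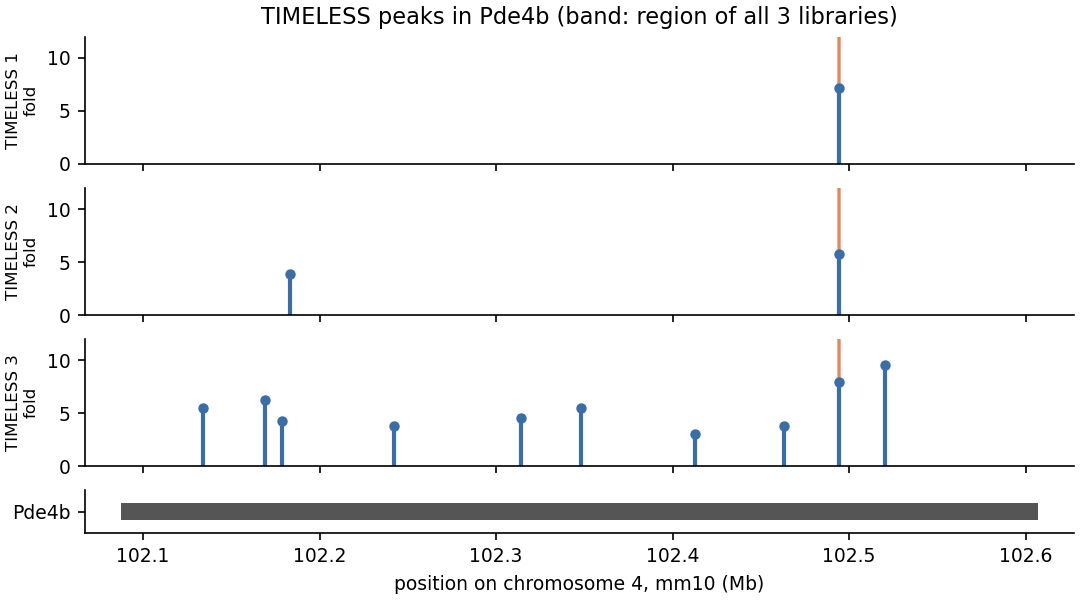
Stems mark the summits of peaks in Pde4b along chromosome 4 in Mb, with fold enrichment as height, in 1 panel for each TIMELESS library; the orange band marks the region of all 3 libraries and the grey bar the gene. The libraries have 1, 2 and 10 peaks in the gene and meet only in the band.

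Among genes of cAMP synthesis and degradation, 10 of 24 held a shared region, or 41.7%, against 35.9% in random lists matched on classes of gene length. In 3 of them, Pde4b, Pde1c and Pde4d, all 3 libraries had a peak in 1 region. The calcium-dependent phosphodiesterase gene Pde1c had a mean fold of 6.21 ± 1.26 (SD, n = 3) on chromosome 6 at 56297099 to 56297567. Pde4d held 8 shared regions and had 3.98 ± 0.319 in the only 1 of all 3 libraries. Pde8b had folds of 5.13 and 5.54 in replicates 2 and 3. The Pde4d region kept a peak in 1 library at −log10 q of at least 5 and in 0 at fold of at least 5. At both settings the Pde4b region kept peaks of 3 libraries and the Pde1c region of 2. The list was not called, with adjusted permutation p = 0.974. The count fell to 4 of 24 without replicate 3, or 16.7% against 21.7% at random, and to 3 of 24 without replicate 2, or 12.5% against 18.97%, so that the direction turned in both. It also turned for regions of all 3 libraries, with 12.5% against 16.7%, at −log10 q of at least 5, with 20.8% against 21.2%, and with random lists of the genes nearest in length, with 41.7% against 42.8%.

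Genes of protein kinase A, Epac and CREB signalling held a shared region in 9 of 33 cases, or 27.3%, against 22.3% at random (adjusted permutation p = 0.974). Akap13 and Akap9, anchors of protein kinase A, had mean folds of 3.93 ± 0.693 and 4.04 ± 1.05 (SD, n = 3). Pkib, an inhibitor of the kinase, had 4.49 ± 1.33, and Rapgef4, which encodes Epac2, had 4.17 ± 0.816. The count was 6 of 33 without replicate 3 and 4 of 33 without replicate 2. At −log10 q of at least 5 it was 3 of 33, or 9.09% against 12.7% at random, so that the direction turned, and of these 4 regions only that of Pkib kept peaks of 2 libraries.

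Of the circadian clock list 2 of 27 genes held a shared region, against 12.6% at random (adjusted permutation p = 0.974). They were the nuclear receptor gene Rora, with a mean fold of 10.5 ± 2.27 (SD, n = 3) on chromosome 9 at 69016078 to 69016865, and Npas2, with folds of 5.13 and 3.63 in replicates 2 and 3. Of the replication fork and DNA damage checkpoint list 3 of 37 held one, against 10.7% at random (adjusted permutation p = 1.00). They were Wdhd1, a replisome factor, with 5.59 ± 1.73, the cohesin subunit gene Stag1 with folds of 8.30 and 6.84 in replicates 1 and 2, and the clamp loader gene Rfc1 with folds of 4.11 and 2.87 in replicates 2 and 3. Without replicate 3 the counts were 1 of 27 and 2 of 37, and without replicate 2 they were 1 of 27 and 1 of 37.

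Synaptic adhesion molecules, with a median gene length of 968.5 kb, held one in 23 of 33 cases, or 69.7%, against 41.1% in random lists matched on classes of length (95% of lists between 24.2 and 57.6). Lrrtm4, a postsynaptic adhesion protein, had a mean fold of 7.89 ± 0.494 (SD, n = 3), and the neurexin relative Cntnap2 had 7.71 ± 1.43. Lrp1b, of the LDL receptor family, had 7.09 ± 2.27, and Cadm2 had 5.93 ± 0.777.

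Synaptic adhesion was the only one of the 18 lists called, with adjusted permutation p = 0.0180. The call ended, and the direction turned, when members were matched to the 100 genes nearest in length, a comparison chosen after seeing the data, with 75.1% in random lists and adjusted permutation p = 1.00. Without replicate 1 the count was 20 of 33 genes, or 60.6% against 36.7% at random, with permutation p = 0.0066 before adjustment and 0.119 after it, so the call was lost while most of the difference stayed. The call was kept without replicate 3 with 19 of 33 genes and adjusted permutation p = 0.0036.

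Ionotropic glutamate receptors and partners held a shared region in 13 of 29 cases, against 32.6% at random (adjusted permutation p = 0.859). Shank2, a postsynaptic scaffold, had a mean fold of 12.5 ± 4.68 (SD, n = 3) and Grin3a, an NMDA receptor subunit, had 9.91 ± 2.03. The AMPA receptor subunit gene Gria3 had 8.14 ± 1.77, and the kainate receptor subunit gene Grik1 had 5.98 ± 0.139. Metabotropic and other G protein-coupled receptors held one in 9 of 28 cases, against 23.3% (adjusted permutation p = 0.941). In that list Htr4 had 10.7 ± 0.0114, Grm7 had 9.54 ± 1.32, Htr2c had 7.17 ± 2.17 and Grm5 had 6.87 ± 3.53. Without replicate 3 the counts were 10 of 29 and 7 of 28. Random lists of the genes nearest in length came close to both lists, with 43.8% against 44.8% and 29.7% against 32.1%.

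The presynaptic release machinery held a shared region in 12 of 26 cases, or 46.2%, against 26.8% at random, with permutation p = 0.0294 before adjustment and 0.265 after it. Beside Rims1, the calcium channel gene Cacna1b had a mean fold of 11.4 ± 0.306 (SD, n = 3), the active zone scaffold gene Bsn had 9.06 ± 0.907 and the vesicle priming gene Unc13b had 6.04 ± 0.886. Activity-regulated and plasticity genes, which include Fos, Arc and Bdnf, held one in 1 of 30 cases, against 11.9% (adjusted permutation p = 0.859). That gene was the kinase subunit gene Camk2d, with folds of 5.13 and 4.78 in replicates 2 and 3. The presynaptic count fell to 8 of 26 without replicate 3, or 30.8% against 15.9% at random, and to 5 of 26 without replicate 2, or 19.2% against 13.9%. Random lists of the genes nearest in length to the presynaptic genes reached 35.6%, with adjusted permutation p = 1.00, and no activity-regulated gene held a region without replicate 2 or 3.

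Marker genes of hippocampal cell types showed no called list. Excitatory neuron markers held a shared region in 4 of 20 cases, with Zbtb20 at a mean fold of 3.83 ± 0.798 (SD, n = 3). Nr3c2 and Cpne4 had shared regions with peaks of 2 libraries each. Interneuron markers did so in 3 of 18 cases, with Adarb2 at 6.97 ± 0.992, Reln at 5.60 ± 0.136 and Erbb4 at 5.51 ± 1.02. Both lists had adjusted permutation p = 0.974. Without replicate 3 the counts were 3 of 20 and 3 of 18, and without replicate 2 they were 2 of 20 and 3 of 18. Random lists of the genes nearest in length reached 18.0% against 20% for excitatory neurons and 18.6% against 16.7% for interneurons, where the direction turned.

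Astrocyte markers held a shared region in 1 of 14 cases (Gli3, 4.13 ± 0.974, SD, n = 3) and microglia markers in 1 of 14 (Itgam, 5.10 ± 0.623), each with adjusted permutation p = 1.00. Vascular markers held one in 4 of 14 cases (adjusted permutation p = 0.941), with the receptor gene Flt1 at 10.1 ± 2.46 and Slco1a4, Abcb1a and Tek in 2 libraries each. Oligodendrocyte lineage markers held one in 0 of 14 cases (adjusted permutation p = 0.974). The vascular count was 3 of 14 without replicate 3, 1 of 14 without replicate 2, where the share of 7.14% fell below the random 8.12%, and 2 of 14 without replicate 1. The astrocyte, microglia and oligodendrocyte counts were the same without replicate 3.

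Control genes of other tissues also held shared regions. Liver genes did so in 2 of 20 cases, or 10.0% against 6.2% at random (Apob and F2, adjusted permutation p = 0.974). Striated muscle genes did so in 1 of 20, or 5.0% against 9.0% at random (Ttn, mean fold 5.37 ± 1.02, SD, n = 3, adjusted permutation p = 1.00). Housekeeping genes, with a median length of 5.29 kb, held one in 0 of 20 cases (adjusted permutation p = 1.00). The liver count was 0 of 20 without replicate 3 and 1 of 20 without replicate 1 or 2, and the muscle and housekeeping counts were the same without replicate 3. Of the 60 named genes with a shared region, 52 kept peaks of 2 libraries there without replicate 3, 49 without replicate 2 and 55 without replicate 1. The naming rule took regions of all 3 libraries first, and these keep 2 libraries whichever is left out. The counts therefore do not test how stable the named regions are.

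**Figure D5:**
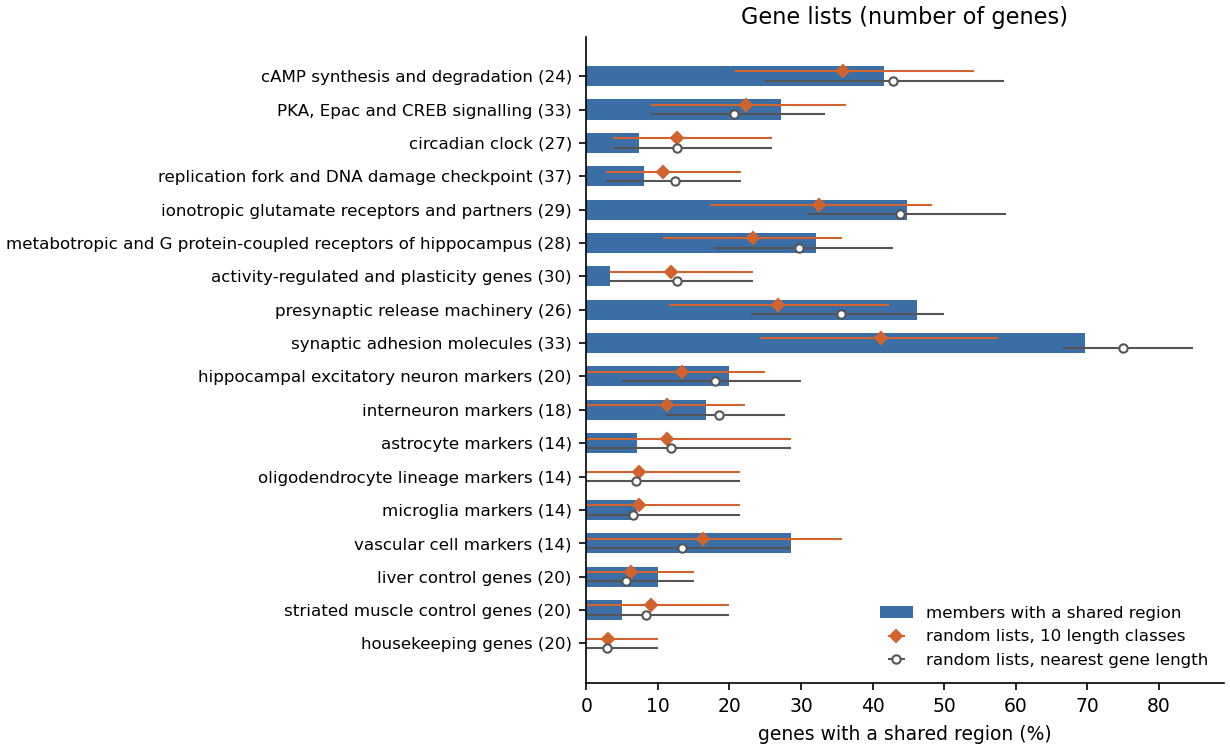
Bars show the percentage of genes in each of 18 lists that hold a region of at least 2 TIMELESS libraries, with list sizes in brackets; diamonds and circles show the mean of 10000 random lists matched on classes of gene length or to the genes nearest in length, with lines for the central 95% of lists. Synaptic adhesion molecules at 69.7% exceed the first kind of random list (41.1%) and lie below the second (75.1%).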

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

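The tests in this part were chosen after the results were seen, except the comparison of synaptic adhesion genes with lists matched on classes of gene length. On the sequence named ribosomic, which the comparisons of the report do not use, TIMELESS replicates 1, 2 and 3 had 11, 17 and 20 peaks, above the 6 peaks of the input. The median pileup of these peaks was 116, 237 and 256 in the TIMELESS libraries and 70.5 in the input. Per 1000000 tags it was 13.8, 17.5 and 8.41 in the TIMELESS libraries and 4.81 in the input. With at most 1 tag kept per position, pileup need not scale with tag number, so these values do not show enrichment. The median fold was 2.47, 1.94, 1.94 and 2.78.

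The library labelled TIMELESS replicate 3 has an input's name in its file header, and it has the most tags and the most peaks. The headers name replicate 1, the input, replicate 2 and replicate 3 as sample_1_S27_L008, input_1_S28_L008, sample_2_S29_L008 and input_2_S30_L008. Samples and inputs thus alternate in these names, which goes with replicate 3 being an input. An input of the same kind as the deposited one is argued against by peak number, as far as 1 input library can show. After scaling to the depth of the input, 2754 of its peaks had −log10 p of at least 12.1, against 6.07 for the weakest input peak. That is 9 times the 306 input peaks, against 2.99 times for replicate 1 and 7.29 times for replicate 2. Replicates 1 and 2 had fewer tags than the input and were not scaled. Replicate 2 had 2.44 times the number of replicate 1, and replicate 3 had 3.01 times that number. Overlap cannot tell a wrong name in the header from an input. Of 4760 regions with peaks of both replicates 1 and 2, merged over all 3 libraries, 73.0% held one of its peaks (71.7 to 74.3). A peak of replicate 3 can join separate peaks of replicates 1 and 2 into 1 such region, which adds to this share. With no control in the calling, an input can share such sites too. Of the peaks of the deposited input, 48.7%, 55.6% and 58.5% overlapped peaks of replicates 1, 2 and 3. A wrong name and an input prepared in another way both stay open, since 1 input library shows no spread between inputs.

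TIMELESS summits were rare within 1 kb of gene ends, at 0.749% ± 0.187 (SD, n = 3). Gene-poor stretches wider than the moves are argued against as the whole cause. Moving each peak by 10 to 500 kb gave 2.56% and all 3 libraries lay below every such draw. Shorter gene-poor stretches stay open, since such a move can carry a peak out of them. A background that the input has too cannot be told apart from binding by TIMELESS, because the input share of 5.88%, above random within 1 kb but not within 3 kb, rests on 1 library with 306 peaks. Repeats and base composition were not tested, since no genome sequence was used here, and they stay open. Binding of TIMELESS away from gene ends stays open as an untested biological explanation.

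Synaptic adhesion genes held shared regions in 69.7% of cases, against 41.1% in lists matched on classes of gene length. Gene length is a candidate explanation, since the longest class runs from 108.5 to 2390 kb and the median of this list is 968.5 kb. Lists matched to the genes nearest in length held shared regions in 75.1% of cases, above the list itself. For the longest members, the genes nearest in length included other members of the list, so this match cannot cleanly separate length from membership. No biological explanation was tested, and a role of TIMELESS at these genes is neither shown nor excluded.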

How the results depend on the processing

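Moving peaks by 10 to 500 kb, nearest-length matching, the gene-end windows and leave-one-out values of peak counts, input overlap and regions of all 3 libraries were chosen after seeing the data. Summits in promoters were not run, because the gene table has no strand. No paired analysis was possible because the input has 1 library. The shares of summits in genes (33.7% to 36.8%, and 26.4% in protein-coding genes) and near gene ends (0.660% to 0.973%, and 3.27% within 3 kb) stayed below random in each alternative.

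At −log10 q of at least 5 the mean fell to 22932 peaks, shared regions to 4956, regions of all 3 libraries to 1544, and overlap with the input rose to 1.95%. At fold of at least 5 these counts were 7984, 2511 and 913. Equal numbers of top peaks gave 3537 and 1056 regions. These counts fell because fewer peaks entered. Leaving out 1 library gave means of 16056 to 56851 peaks, 4193 to 9905 regions of the remaining pair and an overlap with the input of 0.424% to 1.27%. The excess of shared regions over random placement was kept in these settings and with peaks moved by 10 to 500 kb, from 10.2 to 85.3 times. Of the 60 named genes with a shared region, 47 had peaks of 2 libraries there at the stricter q and 44 at the stricter fold.

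The number of called lists was 1 in the main test, 6 without length matching, 0 with nearest-length matching and 0 to 1 without 1 library. It was 0 within 3 kb of gene ends, where 389 of the 21887 protein-coding genes held a shared region. For synaptic adhesion, the difference from random lists turned from 28.6 to -5.37 percentage points with nearest-length matching, which follows gene length more closely. It does not fully remove gene length, since the longest genes shared 1 pool, and that pool held other members of the list. Within 3 kb of gene ends the difference was -1.71, from 0 of 33 genes against 1.71% at random, which decides nothing. Mean rho of 0.633 was 0.555 with −log10 q in place of fold and 0.516 to 0.584 without 1 library, over other sets of regions; the cause was not tested. Replicate 1 had the fewest tags, 8425679, and whether depth limited its peaks was not tested.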

Other observations

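All tests in this part were chosen after the results were seen. Peak density differed between chromosomes in the TIMELESS libraries. Chromosome 11 had the fewest peaks per Mb of the 19 autosomes in each TIMELESS library, at 2.27, 7.29 and 22.6 in replicates 1, 2 and 3, against autosome medians of 2.82, 9.67 and 34.4. Chromosome X had 0.844, 0.671 and 0.912 times the autosome median, and chromosome Y had 0.699, 0.584 and 0.427 times. In the input, chromosome X had 0.376 times and chromosome Y 1.69 times the autosome median.

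On 14 of 21 chromosomes the last peak of all 4 libraries, the input included, ended within 200 bp of the same place. These peaks were among the strongest, with a median fold of 24.0, 24.0 and 23.3 in TIMELESS replicates 1, 2 and 3 and 26.5 in the input. They made up 10, 11 and 9 of the 20 peaks with the largest fold in the TIMELESS libraries and 11 of 20 in the input. On chromosome X these peaks ended between 170881338 and 170881420. Since they lie over input peaks they are in none of the regions of the report.

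One hypothesis was that a region of all 3 libraries in Pde4b is rare among genes of its length, which would need fewer than 5 of the 100 genes nearest in length to hold one. The number was 41, so such a region was common among genes of 462.5 to 581.2 kb, and 89 of them held a region of at least 2 libraries.

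Another hypothesis was that olfactory and vomeronasal receptor genes hold shared regions more often than other genes of their length. Of 1463 such genes 55 did, or 3.76%, against 2.65% in lists matched to the nearest genes in length, with permutation p = 0.0146 and adjusted p = 0.0730 over 5 gene families. In regions with peaks of both replicates 1 and 2, merged over all 3 libraries, the count was 20, with permutation p = 0.404. The hypothesis was therefore not borne out at this threshold. Zinc finger genes (33 of 397), keratin genes (0 of 53), histone genes (1 of 67) and ribosomal protein genes (1 of 97) were not called either.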
